A study of Puccinia emaculata and Phakopsora pachyrhizi with 12 samples.

How the data were processed

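RNA was measured by sequencing in germinating urediniospores of 2 rust fungi, Puccinia emaculata and Phakopsora pachyrhizi, at 0, 10 and 100 mM phosphite, with 2 libraries per species and dose and 12 libraries in all. Per the labels' protocols, spores germinated for 24 h in the dark, total RNA was purified on silica columns, and paired-end reads of 100 bases came from a HiSeq 2000. Groups and replicate numbers were taken from the sample titles. The labels call the 2 libraries of a group biological replicates.

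The deposited files hold 1 table per library, and their values are FPKM (fragments per kilobase of locus and per 1000000 mapped fragments) with a lower and an upper bound, per the file headers, which are those of a Cufflinks gene tracking table. TopHat2 and Cuffdiff are named in the submitters' processing notes, and their versions are not given in the sources used here. Each row is a locus assembled within 1 library on a contig whose name has a component, a subcomponent and a sequence number. The reference columns of the tables (gene name, class code, nearest reference) are empty, so the files pair no contig with a gene name or description. How the contigs were assembled, and from which reads, is not given in the sources used here. Loci were numbered separately in each library, so the contig was the unit of analysis. The FPKM of a contig is the mean over its loci weighted by locus length, and its implied fragments are the sum over its loci. A contig with no locus in a library's table is called unlisted. Between 395 and 1104 contigs were listed in 1 replicate and unlisted in the other replicate of its group, and their median level in the replicate that listed them was 2.70 to 4.30 FPKM. Being unlisted is therefore not a measurement of 0, and some unlisted contigs were abundant in another library.

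FPKM values give no depth by themselves. The upper bound lies 2 SD above the value, and the squared ratio of a value to its SD gives an implied number of fragments. Below 300 implied fragments, 33.4% to 36.0% of these numbers lay within 0.02 of a whole number. Most were thus not whole, so implied fragments are approximate numbers and not exact counts. The smallest implied number in a library was 9.00 to 9.40, where the counting error was 32.6% to 33.3%. The listed loci of a library held 8600518 to 14656350 implied fragments. The median locus held 152 to 194 fragments in Puccinia emaculata and 67.9 to 78.9 in Phakopsora pachyrhizi, which gives a counting error of 7.18% to 8.11% and of 11.3% to 12.1%. These errors cover counting alone.

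Each species was fitted separately with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options) on log2(FPKM + 1), over all 6 libraries of the species with dose as 3 levels. Unlisted contigs entered as 0. Contigs with at least 1 FPKM in 2 or more libraries were tested, which left 7200 contigs in Puccinia emaculata and 7712 in Phakopsora pachyrhizi. The 3 contrasts of a species (10 against 0 mM, 100 against 0 mM, 100 against 10 mM) were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast. A contig is called where its adjusted p is under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low contigs, and plain folds are ratios of mean FPKM. No fold is printed for a contig that is unlisted in both libraries of a group, and calls are split by whether a contig was listed in all 4 libraries compared. The shares of the 10 top loci were compared with 0 mM in a linear model with dose as 3 levels over the 6 libraries of a species, and its 8 p-values were adjusted together by Benjamini-Hochberg. The summaries used pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and the plots used matplotlib 3.10.9.

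The fit was tested on simulated data with 100 contigs changed by log2 1 and 100 changed by log2 2 per contrast. Spreads were drawn from the real ones regardless of contig level, and only contigs above the median level were changed. Each contrast had 1 random draw of the same design. Differences between the contrasts of a species therefore do not measure differences in their power. In Puccinia emaculata, it recovered 22% of the contigs changed by log2 2 and 0% of those changed by log2 1 for 100 against 0 mM, 25% and 1% for 10 against 0 mM, and 0% of either for 100 against 10 mM. In Phakopsora pachyrhizi the shares were 49% and 4% for 100 against 0 mM, 49% and 27% for 10 against 0 mM, and 48% and 2% for 100 against 10 mM. False calls among the unchanged contigs numbered 0 to 9 per contrast.

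The design, the main test and most alternatives were fixed before the data were examined: quantile normalization, median centring, limma without trend or without the robust option, no filter, a filter at 10 FPKM, pseudocounts of 0.1 and 10, only the 2 groups compared, the replicate number as a block, each library left out in turn, and a minimum log2 change of 1. Chosen after the data were seen were a fit of contigs listed in all 6 libraries with and without median centring, components in place of contigs, levels spread over the whole contig, and limma-voom on the implied fragments. The rule for named features, fixed beforehand, took for each species the 2 contigs with the largest rise and the 2 with the largest fall at 100 against 0 mM. They had to be called, to have both treated libraries beyond both control libraries, and to have a mean level at or above the median of tested contigs. Gene lists fixed beforehand could not be applied because no contig has a name. The species share 1402 contig names, but the greatest locus end on such a contig correlated with r = 0.0904 between the species against 0.993 and 0.996 between libraries of 1 species. The names thus come from separate assemblies, and no contig was compared between the species. The overlap of the contrasts that share the 0 mM libraries was set beside 100 draws of unchanged groups simulated with each species' spread. A split of the controls, 10 mM against 1 control library and 100 mM against the other, both ways, was also chosen after the data were seen.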

Results

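The series asked how phosphite, a salt of phosphorous acid used against plant diseases, changes transcript levels in rust fungi that it suppresses. Urediniospores, the wind-borne spores with which rusts spread between plants, germinated for 24 h on solution with 0, 10 or 100 mM phosphite. Puccinia emaculata infects switchgrass, and Phakopsora pachyrhizi causes Asian soybean rust. Each species and dose had 2 libraries. The deposited FPKM tables listed 6022 to 6809 contigs per library in Puccinia emaculata and 6366 to 7209 in Phakopsora pachyrhizi. The listed loci held 10375287 to 14656350 implied fragments per library in Puccinia emaculata and 8600518 to 12905957 in Phakopsora pachyrhizi. In Puccinia emaculata 4747 of 8545 contigs were listed in all 6 libraries, and in Phakopsora pachyrhizi 4768 of 9644. The contigs carry no gene names, so the transcripts are described by level, direction and contig name.

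Over the contigs listed in all 6 libraries of a species, libraries of 1 dose correlated across contigs with r of 0.961 to 0.972 in Puccinia emaculata and 0.958 to 0.969 in Phakopsora pachyrhizi. Contigs are not independent replicates, so these values describe the libraries. Libraries at 0 and 100 mM correlated with r of 0.763 to 0.898 and of 0.858 to 0.884. Libraries at 0 and 10 mM correlated with r of 0.918 to 0.977 in Puccinia emaculata, which covers the range of its replicates. In Phakopsora pachyrhizi they correlated with r of 0.939 to 0.948, below each replicate pair.

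**Figure D1:**
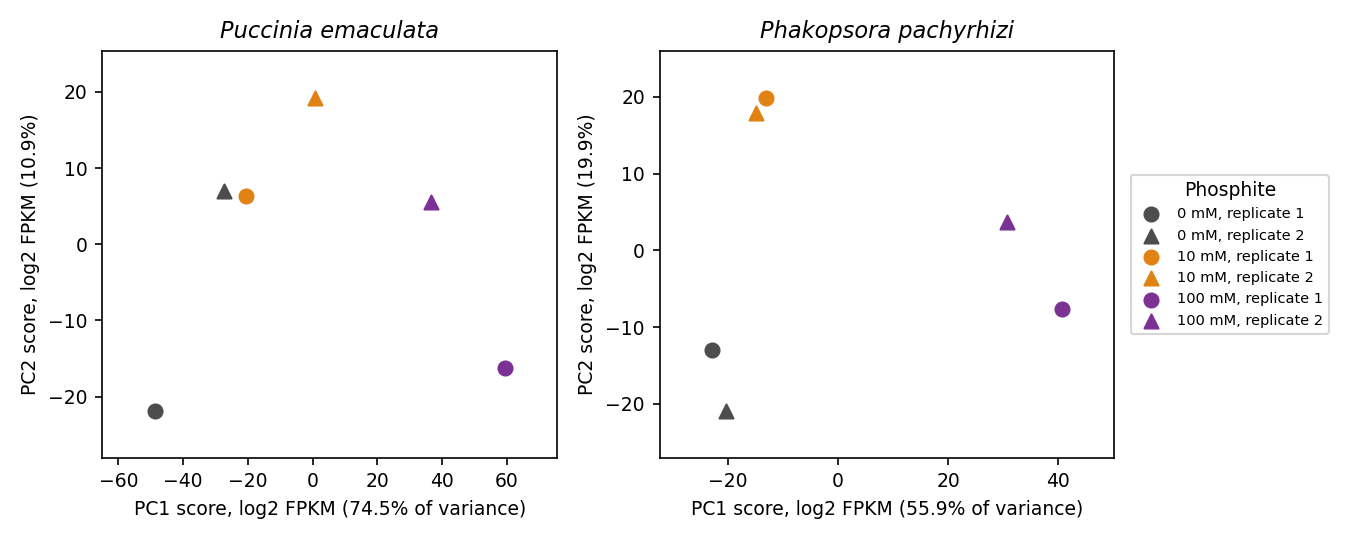
Principal components of log2 FPKM over contigs listed in all 6 libraries of each species, with PC1 and PC2 scores on the axes and 1 point per library (color for the dose, shape for the replicate). PC1 held 74.5% of the variance in Puccinia emaculata and 55.9% in Phakopsora pachyrhizi, and on it both 100 mM libraries lay to the right of the other 4; in Puccinia emaculata the 0 mM libraries scored -48.7 and -27.4 and the 10 mM libraries -20.6 and 0.73.

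In Puccinia emaculata 1659 of 7200 contigs were called at 100 mM against 0 mM phosphite, 730 higher and 929 lower. This was the most calls of its 3 contrasts with all libraries. Leaving out a 0 mM library leaves 1 in that group, so counts from such a fit do not rank the contrasts. Of the 1659 contigs, 476 higher and 533 lower were listed in all 4 libraries, with median log2 fold changes of 1.54 and -1.91. Large falls outnumbered large rises: 121 of the listed contigs were lower by log2 3 or more and 6 were higher by as much. A further 246 higher and 369 lower calls were unlisted in both libraries of the group with the lower value. Regardless of the test, 954 contigs were listed in both libraries of 1 dose and in neither of the other, against 166 and 95 when the same 4 libraries were paired across doses. The median log2 fold change of all tested contigs was -0.18, and median centring moved it to 0.03. The balance of calls depended on the scaling and on single libraries of both doses, with 1054 higher and 940 lower under quantile normalization and 558 higher and 459 lower without 0 mM replicate 2. It was 39 higher and 198 lower without 100 mM replicate 1 and 126 higher and 627 lower without 100 mM replicate 2.

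Abundant transcripts were called in both directions in Puccinia emaculata, and which of them were called depended on single libraries. Of the 100 most abundant contigs listed in all 6 libraries, each with a back-transformed mean of at least 1424 FPKM, 20 were lower at 100 mM, 19 of them by log2 3 or more. Another 14 were higher, by at most log2 2.28, and with median centring 5 were higher and 19 lower. The median log2 fold change of the 100 contigs was 0.92, against -0.18 for all tested contigs. Among the other contigs listed in all 6 libraries, 462 were called higher and 513 lower. The split of the 100 was not shown to differ from theirs (Fisher exact p = 0.491). The group of 100 was chosen after its values were seen. The contig with the most FPKM in both 0 mM libraries, comp22047_c4_seq1, has loci only up to base 218. It held 59412 and 59690 fragments there, 0.573% and 0.407% of those listed, so its rank in FPKM is not a rank in fragments. Contig comp22047_c4_seq1 stood at 76984 ± 16809 FPKM (SD, n = 2) at 0 mM, 52391 ± 22120 at 10 mM and 2696 ± 2522 at 100 mM. It fell 28.6-fold from 0 to 100 mM (log2 fold change -5.23, SE 0.87, adjusted p = 0.0239 by limma). Its adjusted p was 0.119 without 0 mM replicate 1, 0.0647 without 0 mM replicate 2 and 0.0527 without 100 mM replicate 1. The direction of the calls among the 100 turned without 0 mM replicate 2 (23 higher and 1 lower), with quantile normalization (30 and 21) and with limma-voom on implied fragments (28 and 21). It was 0 higher and 29 lower without 100 mM replicate 2 and 2 higher and 11 lower with only the 2 groups compared. Of the 100 contigs, 0 were called without 0 mM replicate 1 (limma, with 53 at an unadjusted p under 0.05), 8 without 10 mM replicate 1, 7 without 10 mM replicate 2 and 5 without 100 mM replicate 1.

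The steepest measured changes between 0 and 100 mM in Puccinia emaculata were in contigs also chosen after their values were seen. Contig comp15282_c0_seq1, with loci up to base 665, rose from 6.11 ± 2.00 FPKM (SD, n = 2) at 0 mM through 27.1 ± 9.89 at 10 mM to 125 ± 2.00 at 100 mM. This is 20.5-fold (log2 fold change 4.18, SE 0.33, adjusted p = 0.0068 by limma). Contig comp21148_c0_seq1, with loci up to base 880, fell from 6163 ± 2271 FPKM at 0 mM through 2800 ± 820 at 10 mM to 66.0 ± 57.4 at 100 mM. This is 93.4-fold (log2 fold change -6.80, SE 0.77, adjusted p = 0.0112 by limma). Without 0 mM replicate 1 the adjusted p of the pair was 0.0529 and 0.0796. The rule fixed beforehand named 4 contigs that were each unlisted in a whole group. Contig comp16017_c1_seq1 (79.4 and 376 FPKM at 100 mM from 13 and 14 fragments) and comp18211_c1_seq1 (132 and 165 FPKM from 58 and 52 fragments) were unlisted at 0 mM. Their adjusted p without 0 mM replicate 1 was 0.0781 and 0.0529. Contig comp18671_c0_seq5 was listed at 2848 and 3530 FPKM at 0 mM and unlisted at 10 and 100 mM. Its sister contig comp18671_c0_seq2, of the same subcomponent, stood at 10997 ± 4067 FPKM at 0 mM and 25839 ± 3301 at 100 mM (adjusted p = 0.0798), so reads may be split differently between them. Contig comp23396_c5_seq4 was listed at 1543 and 1443 FPKM at 0 mM, at 1148 and 973 at 10 mM, and was unlisted at 100 mM.

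How many contigs were called in Puccinia emaculata changed when single libraries were left out, which also leaves a group with 1 library. For 100 against 0 mM the number was 43 without 0 mM replicate 1, 1017 without 0 mM replicate 2, 237 without 100 mM replicate 1 and 753 without 100 mM replicate 2.

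At 10 mM against 0 mM, 72 contigs of Puccinia emaculata were called, 31 higher and 41 lower. All but 3 were unlisted in both libraries of 1 dose. The balance of directions turned with a pseudocount of 0.1, to 51 higher and 21 lower with 50 calls in common, and with a filter at 10 FPKM, to 6 higher and 2 lower. The 3 listed in all 4 libraries are named after their values were seen. Contig comp21101_c0_seq1 rose 3.07-fold, from 38.0 ± 1.86 to 116 ± 21.3 FPKM (SD, n = 2; log2 fold change 1.58, SE 0.17, adjusted p = 0.0416 by limma), and was at 206 and 204 FPKM at 100 mM. Contig comp25439_c0_seq1 rose 14.5-fold, from 31.3 ± 18.1 to 453 ± 43.7 FPKM (log2 fold change 3.93, SE 0.43, adjusted p = 0.0416), and was unlisted at 100 mM. Contig comp14284_c1_seq1 fell 10.1-fold, from 34.4 ± 7.30 to 3.39 ± 0.767 FPKM (log2 fold change -3.01, SE 0.31, adjusted p = 0.0382), and was unlisted at 100 mM. Fitting the contigs listed in all 6 libraries called 0 by limma (596 at an unadjusted p under 0.05), and limma-voom on implied fragments also called 0 (984). The former fit tested only 1 of the 72 contigs. The latter tested 65 of them and called 0, so the 72 calls did not hold in it. In simulation the main test recovered 0% to 25% of contigs changed by log2 2 over the 3 contrasts of this species. Limma-voom was not simulated. The 0 calls thus do not show an absence of response. Leaving out a library gave 0 calls by limma without 0 mM replicate 1 (379 at an unadjusted p under 0.05), 1 without 0 mM replicate 2 or either 10 mM library, 8 without 100 mM replicate 1 and 24 without 100 mM replicate 2.

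Between 10 and 100 mM, 347 contigs of Puccinia emaculata were called, 145 higher and 202 lower at 100 mM. The 79 listed in all 4 libraries comprised 37 higher and 42 lower, with median log2 fold changes of 1.39 and -2.59, and 12 were lower by log2 3 or more. With a pseudocount of 10 the balance turned to 101 higher and 74 lower. Limma-voom on the implied fragments called 0 contigs in this contrast (2040 at an unadjusted p under 0.05). The number was 1 without 10 mM replicate 1, 117 without 10 mM replicate 2, 26 without 100 mM replicate 1, 125 without 0 mM replicate 1 and 169 without 0 mM replicate 2. Without 100 mM replicate 2 it was 355, of which 11 were higher and 344 lower, and without 100 mM replicate 1 the split was 2 and 24.

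**Figure D2:**
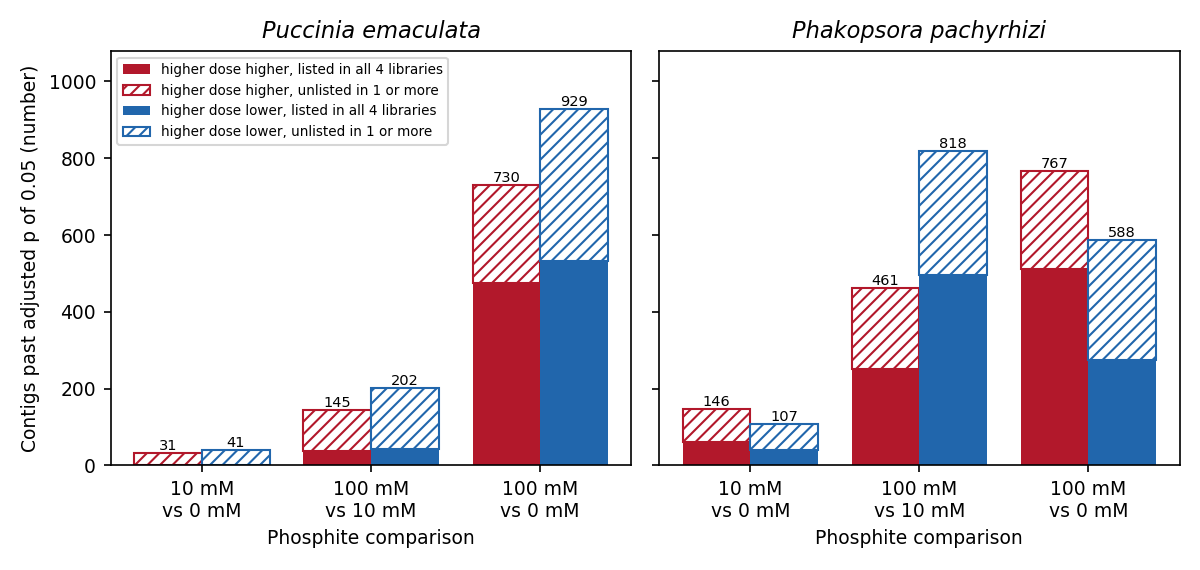
Number of contigs past an adjusted p of 0.05 by limma in each contrast, split by direction and by whether the contig was listed in all 4 libraries compared (filled) or unlisted in 1 or more (hatched). For 100 against 0 mM the bars reach 730 and 929 in Puccinia emaculata and 767 and 588 in Phakopsora pachyrhizi.

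In Phakopsora pachyrhizi, 1355 of 7712 contigs were called at 100 mM against 0 mM, 767 higher and 588 lower. This balance turned without 100 mM replicate 1 (174 higher, 281 lower), without 100 mM replicate 2 (307 higher, 697 lower) and without 0 mM replicate 2 (187 higher, 199 lower). It also turned for limma without trend (552 and 560), for limma-voom on implied fragments (1113 and 1200) and for calls of at least log2 1 (424 and 514). Of these, 511 higher and 274 lower contigs were listed in all 4 libraries, with median log2 fold changes of 0.79 and -1.38. Changes of log2 3 or more again lay mostly on the lower side, with 45 listed contigs lower and 9 higher. A further 254 higher and 302 lower calls were unlisted in both libraries of the group with the lower value. In all, 841 contigs were listed in both libraries of 1 dose and in neither of the other, against 168 and 222 when the 4 libraries were paired across doses. Among contigs listed in all 6 libraries, the most abundant quartile held 235 higher and 63 lower calls, and the least abundant quartile 45 higher and 56 lower. For the most abundant quartile the split was 266 and 115 with median centring and 232 and 106 with quantile normalization. Of the 100 most abundant, a group chosen after its values were seen, 25 were higher and 5 lower, and 7 were higher by log2 2 or more. The split was 25 and 13 with median centring 18 and 11 with quantile normalization and 33 and 24 with limma-voom on implied fragments. The number called among these 100 was 8 without 0 mM replicate 1 and 9 without 0 mM replicate 2.

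The rises among abundant contigs of Phakopsora pachyrhizi included the contig with the most FPKM in both 100 mM libraries, comp24874_c0_seq1, which was chosen after its values were seen. It stood at 6627 ± 1330 FPKM (SD, n = 2) at 0 mM, 14497 ± 415 at 10 mM and 36063 ± 12888 at 100 mM. It rose 5.44-fold from 0 to 100 mM (log2 fold change 2.41, SE 0.30, adjusted p = 0.0136 by limma), with an adjusted p of 0.0724 without 0 mM replicate 1 and 0.0610 without 0 mM replicate 2. Contig comp11632_c0_seq1, with loci up to base 1358, rose from 24.3 ± 1.25 FPKM at 0 mM through 50.8 ± 0.576 at 10 mM to 727 ± 73.5 at 100 mM. This is 29.9-fold (log2 fold change 4.84, SE 0.10, adjusted p = 0.000479 by limma). Contig comp12322_c0_seq1, with loci up to base 1058, fell from 148 ± 8.53 FPKM at 0 mM to 3.44 ± 0.0566 at 10 mM and 1.51 ± 0.310 at 100 mM. This is 98.0-fold (log2 fold change -5.89, SE 0.16, adjusted p = 0.00075 by limma). Most of its fall was present at 10 mM (log2 fold change -5.06, adjusted p = 0.0029). This rise and this fall had the largest log2 fold changes among contigs listed in all 4 libraries and were also chosen after their values were seen.

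The rule fixed beforehand named 4 contigs of Phakopsora pachyrhizi, each unlisted in a whole group. Contigs comp17040_c2_seq1 and comp17040_c0_seq1, of 1 component, were unlisted at 0 mM and stood at 3865 ± 949 and 3605 ± 870 FPKM (SD, n = 2) at 10 mM and at 1842 ± 10.3 and 1591 ± 21.3 FPKM at 100 mM. Contig comp23999_c0_seq1 stood at 12199 ± 2057 FPKM at 0 mM and 20394 ± 253 at 10 mM, from 230070 to 412036 fragments, and was unlisted at 100 mM. Contig comp15981_c1_seq1, with loci up to base 228, stood at 475 ± 8.21 FPKM at 0 mM and 55.2 ± 10.4 at 10 mM. These levels came from 201 and 83 fragments at 0 mM and 47 and 43 at 10 mM, and the contig was unlisted at 100 mM. The direction of the first 3 in this contrast rests on counting an unlisted, otherwise abundant contig as 0, and contig comp23719_c4_seq1 of this species, at 53327 FPKM in 0 mM replicate 2 and 47789 in 10 mM replicate 1, was unlisted in the other 4 libraries. Limma-voom on implied fragments put comp15981_c1_seq1 at an adjusted p of 0.0873. The count of calls for 100 against 0 mM was 404 without 0 mM replicate 1, 386 without 0 mM replicate 2 and 455 without 100 mM replicate 1.

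**Figure D3:**
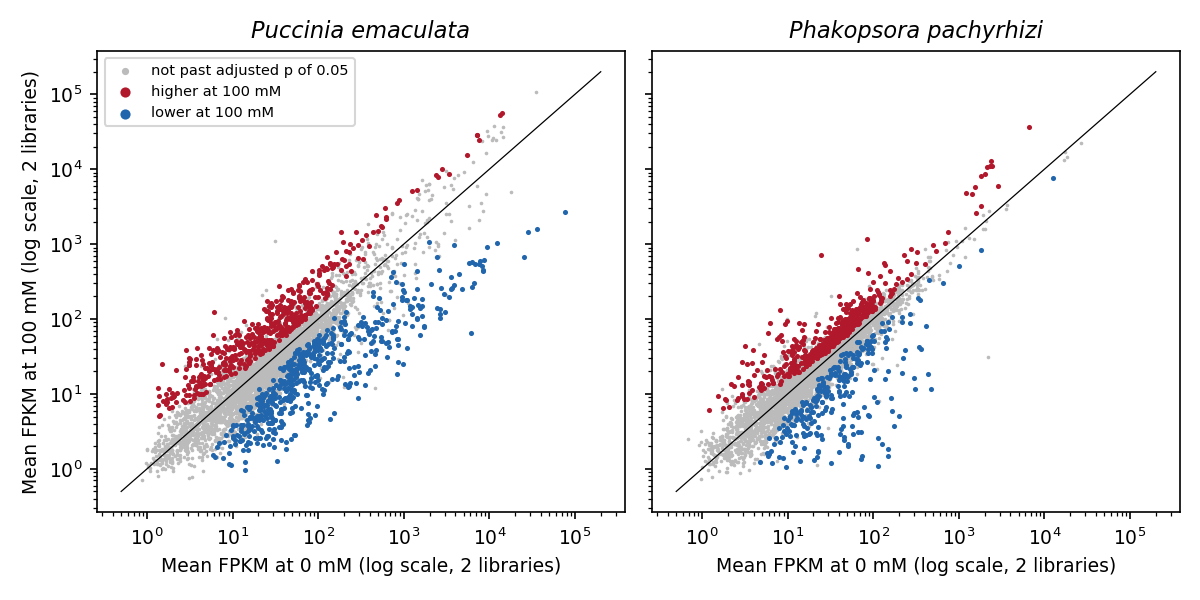
Mean FPKM at 100 mM against mean FPKM at 0 mM, both on log scales with 2 libraries per mean, for contigs listed in all 4 libraries, with 1 point per contig and a line at equal levels. Points called higher number 476 in Puccinia emaculata and 511 in Phakopsora pachyrhizi, and points called lower number 533 and 274.

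At 10 mM against 0 mM, 253 contigs of Phakopsora pachyrhizi were called, 146 higher and 107 lower. Of these, 60 higher and 40 lower contigs were listed in all 4 libraries, with median log2 fold changes of 0.71 and -2.09, and 10 were lower by log2 3 or more against 1 higher. The direction of the balance depended on the scaling and on other settings. It was 54 higher and 62 lower with no filter, 30 and 37 with a filter at 10 FPKM, 83 and 86 with a pseudocount of 10, 99 and 102 for calls of at least log2 1, 29 and 44 over contigs listed in all 6 libraries and 69 and 204 with limma-voom. The median of all tested contigs was 0.23 higher at 10 mM on the log2 scale, and median centring gave 87 higher and 119 lower calls and quantile normalization 84 and 115. Leaving out a library left 5 calls without 0 mM replicate 1, 7 without 0 mM replicate 2, 3 without either 10 mM library, 87 without 100 mM replicate 1 and 83 without 100 mM replicate 2.

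Between 10 and 100 mM, 1279 contigs of Phakopsora pachyrhizi were called, 461 higher and 818 lower at 100 mM. Those listed in all 4 libraries were 250 higher and 496 lower contigs, with median log2 fold changes of 1.00 and -1.06. The median of all tested contigs was -0.22 in this contrast, and the split became 671 higher and 759 lower with median centring and 718 higher and 589 lower with quantile normalization. The count was 146 without 10 mM replicate 1, 168 without 10 mM replicate 2, 247 without 100 mM replicate 1 and 795 without 0 mM replicate 2. The split was 50 higher and 197 lower without 100 mM replicate 1 and 183 higher and 1012 lower without 100 mM replicate 2.

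The contigs called at 10 mM overlapped those called at 100 mM, both against 0 mM. In Puccinia emaculata 26 contigs were higher and 39 lower at both doses, and 1 went opposite ways, where lists drawn independently would share 3.14 and 5.29. In Phakopsora pachyrhizi 61 were higher and 91 lower at both doses, and 2 went opposite ways, where independent lists would share 14.5 and 8.16. All but 3 of the 72 calls of Puccinia emaculata at 10 mM were unlisted in both libraries of 1 dose. Its overlap thus rests mostly on unlisted contigs entered as 0. Over contigs listed in all 6 libraries it had 0 calls at 10 mM and 0 shared. Phakopsora pachyrhizi there shared 13 higher and 40 lower, where independent lists would share 3.61 and 3.94. Unchanged groups simulated against shared controls gave 0 shared calls in either direction, but at most 1 call of any kind, so this value does not measure what shared controls add beside real changes. Across contigs the log2 fold changes of the 2 doses correlated with r = 0.654 in Puccinia emaculata and 0.436 in Phakopsora pachyrhizi, and shared controls alone gave r of 0.498 and 0.496 in the simulation. The covariance was 1.10 against a simulated 0.313 in Puccinia emaculata, a difference of 0.784, and 0.647 against 0.336 in Phakopsora pachyrhizi, a difference of 0.311. With 10 mM set against 1 control library and 100 mM against the other, so that the fold changes share no library, the covariance was 0.842 and 0.644 in Puccinia emaculata (r of 0.452 and 0.393) and 0.273 and 0.252 in Phakopsora pachyrhizi (r of 0.172 and 0.153). Shared calls then numbered 0 and 0, and 3 and 2, with few contigs called at 10 mM against 1 control, so part of the excess of shared calls may come from the shared controls. The overlap of calls in Puccinia emaculata was 0 without 0 mM replicate 1, 1 without 0 mM replicate 2 or either 10 mM library, 7 without 100 mM replicate 1 and 19 without 100 mM replicate 2. In Phakopsora pachyrhizi it was 3 and 4 without 0 mM replicates 1 and 2, 2 without either 10 mM library, and 57 and 53 without 100 mM replicates 1 and 2.

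The share of the FPKM total taken by the 10 loci with most FPKM in Puccinia emaculata went from 24.6% ± 1.16 (SD, n = 2) at 0 mM through 27.9% ± 1.84 at 10 mM to 35.4% ± 2.19 at 100 mM. In Phakopsora pachyrhizi it was 36.0% ± 5.50, 36.2% ± 2.02 and 35.0% ± 3.40. The share of implied fragments taken by the 10 loci with most fragments was 20.3% ± 1.19 at 0 mM, 17.3% ± 0.984 at 10 mM and 20.3% ± 0.600 at 100 mM in Puccinia emaculata, and 28.5% ± 5.62, 29.1% ± 2.69 and 41.2% ± 8.20 in Phakopsora pachyrhizi. In a linear model with dose as 3 levels, chosen after the values were seen, none of 8 differences from 0 mM passed an adjusted p of 0.05. The FPKM share of Puccinia emaculata at 100 mM came nearest, at 10.8 points above 0 mM (95% interval 5.12 to 16.5, unadjusted p = 0.00903, adjusted p = 0.0723). Its fragment share at 10 mM differed from 0 mM by -3.03 points (unadjusted p = 0.0509, adjusted p = 0.204). In Phakopsora pachyrhizi the fragment share at 100 mM was 12.7 points above 0 mM (95% interval -6.23 to 31.6, adjusted p = 0.326), and 6.90 points without 100 mM replicate 1 and 18.5 without 100 mM replicate 2. The responses of the species stand side by side without a test of their difference.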

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

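Of the contigs chosen later, 10 were followed through the alternatives and none turned direction. The 8 named by rule are unlisted in a whole group and enter each alternative as 0 there, so their direction could not turn. Calls at 100 against 0 mM stayed within 1.5 times their number in Puccinia emaculata (Pe) under every alternative with all libraries, while those at 10 against 0 mM often did not. Elsewhere below, Pp is Phakopsora pachyrhizi, "low" is 10 against 0 mM, "high" 100 against 0 mM, "step" 100 against 10 mM and "shared" the calls shared by low and high. Where an alternative tests no fewer contigs or libraries, the cause was not tested. No filter gave Pe low 34, shared 29, and Pp low 116, shared 76. A filter at 10 FPKM gave Pe low 8, step 83, shared 7, and Pp low 67, high 871, shared 53. A pseudocount of 0.1 gave Pp low 500, shared 282. A pseudocount of 10 gave Pe low 38, step 175, shared 32, and Pp shared 98. Limma without trend gave Pe low 167, shared 145. Limma without the robust option gave Pe low 134, shared 116, and Pp low 429, shared 245. Only the 2 groups compared gave Pe low 16 and Pp low 134. Chosen after the data were seen, contigs listed in all 6 libraries gave Pe low 0 (limma, 596 at unadjusted p under 0.05), step 141, shared 0, r 0.762, and Pp low 73, shared 53. With median centring of these, Pe low was 0 (limma, 604 at unadjusted p under 0.05), shared 0, r 0.762, and Pp low 58, shared 44. Levels spread over the whole contig gave Pe low 116, shared 108, and Pp low 447, shared 255. Limma-voom on implied fragments gave Pe low 0 (984 at unadjusted p under 0.05), step 0 (2040), shared 0, and Pp high 2313, step 2335. Leaving out 1 library assumes that the lone sample varies like the other groups. It gave Pe low 0 (limma, 379 at unadjusted p under 0.05) to 24, high 43 to 1442, step 1 to 355, shared 0 to 19, r 0.465 to 0.737, and Pp low 3 to 87, high 386 to 1004, step 146 to 1195, shared 2 to 57, r 0.380 to 0.517. Samples share only a replicate number, and the replicate differences correlated between doses with r of 0.351, -0.00617 and -0.128 (Pe) and 0.000589, -0.0577 and 0.0522 (Pp). With that number as a block, Pe low was 1, step 63, shared 1, and Pp low 5, high 592, step 357, shared 3. Under the block 10 of the 100 most abundant Pe contigs were called, against 34. Their direction turned, to 6 higher and 4 lower from 14 higher and 20 lower. In the same fit comp22047_c4_seq1 had an adjusted p of 0.0514 and Pp comp17039_c2_seq1 of 0.0833. In simulation the test recovered 22% (Pe) and 49% (Pp) of contigs changed by log2 2 at 100 against 0 mM. There 100 contigs changed by log2 2 and 100 by log2 1, against 1659 (Pe) and 1355 (Pp) real calls. The Benjamini-Hochberg threshold loosens with more calls, so these shares do not say how many real changes of that size went uncalled. Gene lists and a comparison of contigs between species were not run, because no contig has a name and the assemblies are separate.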

Other observations

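Tests of abundant contigs, components and the patterns below were chosen after the result was seen, and of the predictions only those on replicate spread and on effective length were written before their result. Contigs of 1 component often moved together between 0 and 100 mM. In Puccinia emaculata 54 of 66 components with 2 or more called contigs had all calls in 1 direction, against a mean of 29.2 and at most 44 in 1000 permutations. In Phakopsora pachyrhizi 27 of 30 did, against a mean of 13.9 and at most 22. Both permutation p-values were 0.001, the smallest that 1000 permutations give. For 100 against 10 mM it was 28 of 38 in Phakopsora pachyrhizi (mean 19.2, permutation p = 0.005) but 3 of 6 in Puccinia emaculata (mean 3.05, permutation p = 0.662). For 10 against 0 mM it was 3 of 3 in Phakopsora pachyrhizi (mean 1.28, permutation p = 0.069), and Puccinia emaculata had 0 such components. Reads shared between related contigs were not tested as a reason.

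In Phakopsora pachyrhizi 4 abundant contigs, comp24874_c0_seq1, comp24875_c0_seq1, comp24877_c0_seq1 and comp19254_c0_seq1, were 4.58 to 5.44-fold higher at 100 than at 0 mM, with adjusted p of 0.00849 to 0.0136. All 4 calls ended without 0 mM replicate 1, with adjusted p of 0.0724, 0.0657, 0.0686 and 0.0547 in that order, and the first 3 without 0 mM replicate 2 (0.0610, 0.0543 and 0.0577). The call of comp24875_c0_seq1 also ended with quantile normalization (0.0762). Contig comp17039_c2_seq1, with more FPKM at 0 mM than these 4, was lower at 100 mM (log2 fold change -0.72, adjusted p = 0.0287). Its call ended without either 0 mM library (0.132 and 0.0992), either 10 mM library (0.0736 each) or 100 mM replicate 1 (0.0746). It also ended for limma without trend (0.0613) or the robust option (0.105) and with only the 2 groups compared (0.0648).

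Contig comp23719_c4_seq1 of Phakopsora pachyrhizi was listed at 53327 FPKM in 0 mM replicate 2 and 47789 FPKM in 10 mM replicate 1, and was unlisted in the other 4 libraries. A limit on fragments per locus could account for this at 0 and 10 mM. There the replicate without the contig had 3.27 M and 1.01 M (M, 1000000) more mapped but unlisted fragments. At 0 mM this replicate also had more mapped fragments, 23.95 M against 19.47 M, so depth may give part of that excess. At 100 mM neither replicate listed the contig, and mapped but unlisted fragments were 8.63 M (replicate 1) and 11.01 M (replicate 2). The libraries that listed it had 10.87 M (0 mM) and 9.599 M (10 mM), so replicate 1 fell below both and replicate 2 above both. The fullest listed locus held 939835 fragments, with 3 within 20% of 1000000. Random failure of locus assembly could not be told from such a limit: of contigs over 60000 fragments 7.14% (2 of 28) were listed in 1 of 2 replicates of a dose, against 2.16% (37 of 1716) of those with 1000 to 60000 fragments (Fisher exact p = 0.128). Contig comp23719_c4_seq1, which prompted the test, is 1 of these 2, so the share partly restates its pattern. This test replaced an earlier one, whose prediction was written before but whose result had been seen by then. There 17.9% (5 of 28, the same contig among them) against 3.03% (52 of 1716) were unlisted in any library. This counted for random failure as worded, although a failure regardless of level predicts equal shares. No biological explanation was tested, and the direction of abundant contigs unlisted in a whole group, comp23999_c0_seq1 and the comp17040 pair among them, stays open.

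In Puccinia emaculata the replicates of each dose spread along the dose axis. Their PC1 scores were -48.7 and -27.4 at 0 mM, -20.6 and 0.73 at 10 mM, and 59.3 and 36.7 at 100 mM. Only the 0 and 100 mM pairs were tested. The 0 mM replicate difference correlated with 10 minus 100 mM at r = 0.315 across contigs once level and length were removed, and at 0.274 before. A bootstrap over contigs put the former at 0.280 to 0.351. Contigs are not independent replicates, so this interval leaves out the spread between libraries. A difference in progress or exposure between replicates might be present but could not be told. The 100 mM replicate difference correlated with 10 minus 0 mM at r = 0.220 once level and length were removed, and at 0.184 before. A trend with contig level or length did not account for the spread at 0 mM, since removing both changed its r by a ratio of 1.15.

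The 10 loci with most FPKM in Puccinia emaculata held a share of the FPKM total 10.8 percentage points larger at 100 than at 0 mM, a difference that did not pass the threshold (adjusted p = 0.0723). A different effective length applied to short loci in the FPKM values did not account for it. Fragments per FPKM and base of loci under 300 bases, relative to loci of 2000 bases and more, changed by 0.0667%. This ratio reflects only the correction made in computing FPKM. It cannot show a difference in fragment length between libraries that was left uncorrected. Whether short loci with few fragments weigh heavily stays open: their share of fragments was 2.40 points larger, but a rise in proportion would be 4.56 points and would meet the bound written for that explanation by itself. The loci also include well covered ones, such as comp20038_c2_seq2 with 18556 and 55133 fragments at 0 mM and 116846 and 103252 at 100 mM. This contig is itself short, with loci only up to base 235. At 100 mM it held 9.15% and 8.01% of the FPKM total but 0.892% and 0.783% of the fragments. It therefore does not speak against a heavy weight of short loci. Its own change was not called (adjusted p = 0.0758 by limma). No biological explanation was tested.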
